A study of Danio rerio with 6 samples.

How the data were processed

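RNA sequencing of whole zebrafish embryos (AB strain, 33 hours post fertilization) was used, with 3 wild-type libraries and 3 libraries of rbm24a mutants. Per the labels, RNA was taken with Trizol, libraries were made with a TruSeq RNA kit, and 100 bp paired ends were read on a HiSeq 2000. The labels give the mutation as an 8 bp deletion made with TALENs, site-specific nucleases, and place it in a different exon for each mutant library, so its exon is not stated here. Groups were taken from the sample labels. The labels call the samples independent without saying whether each came from a separate clutch, so p-values of single genes measure the spread between these samples. The sign, Fisher's exact and permutation tests take genes as the units, so their p-values do not measure that spread.

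The authors deposited whole-number read counts per gene for all 31624 genes of their table, with the symbol and exonic length of each gene. Bcl2fastq 2.17.1.14, cutadapt, HISAT2 2.0.1, HTSeq 0.6.1, DESeq2 and the zebrafish assembly GRCz11 are named, without role or order, per the submitters' processing notes. The authors also deposited FPKM values, which equalled the count divided by exonic length and by the library's total gene count, within 0.005. Whether the counting used strand, and how it treated reads that fit several gene copies, is not given in the sources used here, so genes with near-identical copies, and genes that overlap others, are uncertain. A second table deposited by the authors holds log2 fold changes, p-values and adjusted p-values of genes past a threshold. Its counts equalled those of the table of all genes for all 743 of its genes.

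The authors deposited splicing events in sheets for skipped exons, retained introns, mutually exclusive exons, alternative 5' splice sites and alternative 3' splice sites. Each event has inclusion levels as a fraction between 0 and 1, inclusion and skipping read counts, and a p-value with a false discovery rate (FDR). The tool behind them is not given in the sources used here. Part of the count cells had their 3 counts merged into 1 number, and these were parted in each way that gave back the deposited levels within 0.00051. Tested on 1000 simulated cells, this recovered 1000, with more than 1 solution in 11. The wild-type group was taken as the sample named earlier in the labels' name of the comparison. As a check, 28 of 32 genes with at least a 2-fold change in expression and at least 100 junction reads had their junction reads change in the direction of their gene counts. The sheet of alternative 3' splice sites states 1030 events, and the 556 held here are all lower in the mutant, so no direction was counted for this type and the remainder was not analysed here. Levels within a cell carry no replicate number, so single levels are not tied to a library.

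Counts were tested with edgeR 4.0.16 (R 4.3.3), using TMM scaling and the quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are mutant minus wild-type. The design fixed before the data were examined named limma on log2(FPKM + 1), with edgeR in its place if the table held whole-number counts, which it did. Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested, which left 16489. On counts simulated for this comparison with 16489 genes, the test recovered 21 of 50 genes changed 1.5-fold, 40 of 50 changed 2-fold, 49 of 50 changed 4-fold and 50 of 50 changed 8-fold. It called 15 of 16289 unchanged genes. A fold against a group at 0 was computed against a floor of 3 counts over the group and is a lower bound. Such floors cover counting error only. Standard errors come from the quasi-likelihood fit and take in the spread between libraries.

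Before the data were examined, 32 gene lists were fixed, for lens, muscle, heart, blood, other tissues, stress responses and RNA processing. They were tested with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists. Camera sets the members of a list against the other genes. The correlation estimated from these data was 0.529 for the crystallins and 0.93 for the ribosomal proteins, far above the preset. Simulated on 16489 genes with 1 of 32 lists lowered 1.5-fold, camera called that list and 0 others. The counts were drawn independently for each gene, so this does not cover lists whose members vary together. Members were matched by the symbols of the table, which held 1029 of 1120 symbols, and 42 more were found by gene identifier through a table of gene names. This second step was chosen after a first look at the results. With the table's symbols alone the erythroid list passed (adjusted p of 0.0046 by camera) and with the fuller match, which adds embryonic globins, it did not (adjusted p of 0.0515). The fuller match is the one reported. For the muscle splicing test, names were first taken from the table of gene names, which missed most members, and then from exact symbols of the authors' table, which missed a copy marked as 1 of many. The exact symbols gave p = 0.058 by Fisher's exact test at an FDR under 0.05 and p = 0.0484 by Fisher's exact test at an FDR under 0.01, and the match reported here gave p = 0.0829 and 0.0717.

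Genes with clone-type names were counted and not named. The named genes follow a rule fixed before the data were examined. They are rbm24a, the 10 largest changes in each direction among called genes with separate groups and a mean of at least 2 FPKM, and up to 4 members of each list by smallest p, or 2 where no member was called. The rule adds cpeb1b, pabpc1l and rbm24b. A few items that these rules and lists take are not reported here. For skipped exons it takes the 8 largest changes in each direction with FDR under 0.05 and at least 20 reads in every library, for each other type the 2 largest, and up to 8 skipped exons of the muscle list by smallest FDR. Other list members that are named complete counts of 5 or fewer and were chosen after their values were seen.

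Splicing directions were tested per type with a two-sided exact sign test with 1 event per gene, the smallest FDR. The muscle list, and the overlap of spliced with changed genes, were tested with a two-sided Fisher's exact test. Gene order was taken from GRCz12tu, another assembly than the authors', only for which genes neighbour each other. It placed 14032 of the 16489 tested genes, after 85.8% had matched. Permutations of gene labels numbered 10000. On simulated labels the permutation test of neighbours gave p = 0.1798 with 0 planted blocks and p = 0.001 with 40.

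Alternatives fixed in advance were filters of none and of 5 FPKM, DESeq2-type size factors, DESeq2 1.42.0, limma with pseudocounts of 1, 0.5 and 0.1 FPKM, quantile and median-of-ratios scaling, no abundance trend, robust fitting, a replicate block, a 2-fold minimum, leaving out each library, and stricter splicing filters. For lists they were camera with an estimated correlation and fry. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries and not from the genes. Hardly any list could then pass the adjustment, so a call lost in that setting says little by itself. Scaling by library totals alone, removal of a length trend, list matching by the table's symbols alone and muscle splicing members by exact symbol were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were also used.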

Results

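Transcripts were counted in whole zebrafish embryos at 33 hours post fertilization, in 3 wild-type libraries and 3 libraries of embryos mutant for rbm24a, which encodes an RNA-binding protein. The title of the series names the accumulation of lens crystallins as the subject of the study. Total counts were 13242789, 13733866 and 14416794 in wild-type replicates 1 to 3 and 14100805, 13905380 and 16043155 in mutant replicates 1 to 3. The leading principal component held 60.4% of the variance and separated the groups. The next held 19.3%, with mutant replicate 2 at a score of -41.2 and the other mutants at 22.8 and 12.5. Wild-type replicate 2 was at -14.75 on it and the other wild-type libraries at 10.79 and 9.85. Every pair of replicates within a group differed by more than sampling noise (chi-square per gene between 3.63 and 23.5), so all 6 libraries were counted.

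**Figure D1:**
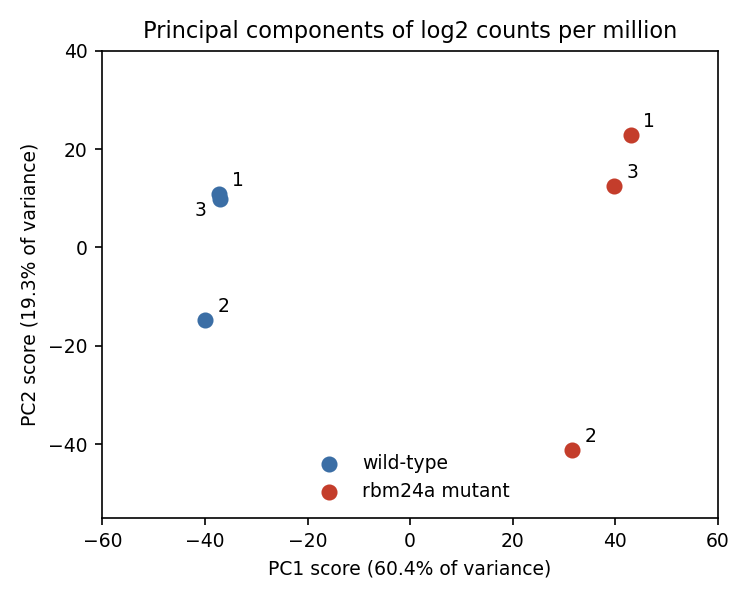
Scores of each library on the leading principal components of log2 CPM, which are unitless, with the replicate number beside each point. The groups separate along the horizontal axis, and mutant replicate 2 lies at -41.2 on the vertical axis.

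The mutated gene itself was measured in every library. Rbm24a (ENSDARG00000102995) had 204, 247 and 211 reads in wild-type and 288, 514 and 366 reads in mutant embryos. Its level was 4.91 ± 0.539 FPKM (SD, n = 3) in wild-type and 8.20 ± 2.74 FPKM (SD, n = 3) in mutants, a log2 change of 0.77 (SE 0.16). It was called higher by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.00571). A deletion of 8 bp hardly alters the length over which reads are counted, so this level does not check the labels. The call was lost with limma on log2(FPKM + 1), with an adjusted p of 0.0711, and over all alternatives the adjusted p lay between 8.3e-05 and 0.0711. Its paralog rbm24b had 4, 16 and 8 reads against 5, 17 and 8, and a difference was not detectable at this depth.

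Lens transcripts were lower in the mutants. Of 36 tested crystallin genes, which encode the main proteins of the lens, 34 fell and none rose, with a median log2 change of -1.61. Crystallins took 0.397%, 0.374% and 0.322% of the reads in the wild-type libraries and 0.182%, 0.170% and 0.171% in the mutant libraries. Among the gamma-crystallins of the crygm2d family, crygm2d2 (ENSDARG00000086917) was at 17.5 ± 1.65 FPKM (SD, n = 3) in wild-type and 1.21 ± 0.0651 FPKM (SD, n = 3) in mutants, a log2 change of -3.79 (SE 0.21). Crygm2d1 changed by -3.18, crygm2d18 by -2.22 and crygm2d17 by -1.97 on the log2 scale. These genes are near-identical tandem copies and their single values are uncertain. The other tested members were cryba1a at -1.06 and crygn1 at 0.01, which did not pass.

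The list of other lens genes also fell, with 10 of 27 tested members lower and 1 higher. Mipa and mipb, lens water channels, changed by -1.23 (SE 0.14) and -1.27 (SE 0.15) on the log2 scale. Cx23, a connexin, changed by -1.08 and lctlb, a lactase-like gene, by -2.54. The member that rose was caprin2, an RNA-binding protein gene, at 1.79. Camera called the crystallins (adjusted p = 3.59e-71) and the other lens genes (adjusted p = 8.73e-05), with Benjamini-Hochberg adjustment over 32 lists. The call on the crystallins was lost with an adjusted p = 0.283 with an estimated correlation, and that on the other lens genes with an adjusted p = 0.491 with an estimated correlation. With 6 libraries that setting has few degrees of freedom, so hardly any list could pass adjustment over 32. Fry, which tests whether members move on balance 1 way, called both lists lower (adjusted p = 0.0134 and 0.0141). Adjusted over the list alone, 35 crystallins were lower and 0 higher, and 13 other lens genes were lower and 2 higher. In mutant replicate 2, which stood apart on the principal components, the crystallins had a median log2 difference of -0.30 from the other mutants. Genes with short transcripts were lower in that library in general. The median log2 difference was -0.26 among 1585 short genes (median 976 bp) and -0.03 among 1584 long ones (median 4683 bp). In wild-type replicate 2 the same medians, against the other wild-type libraries, were -0.15 and 0.05. With the length trend removed, the crystallin difference in mutant replicate 2 was -0.28. The trend may also bear on the values of other lists in that library, which was not tested.

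**Figure D2:**
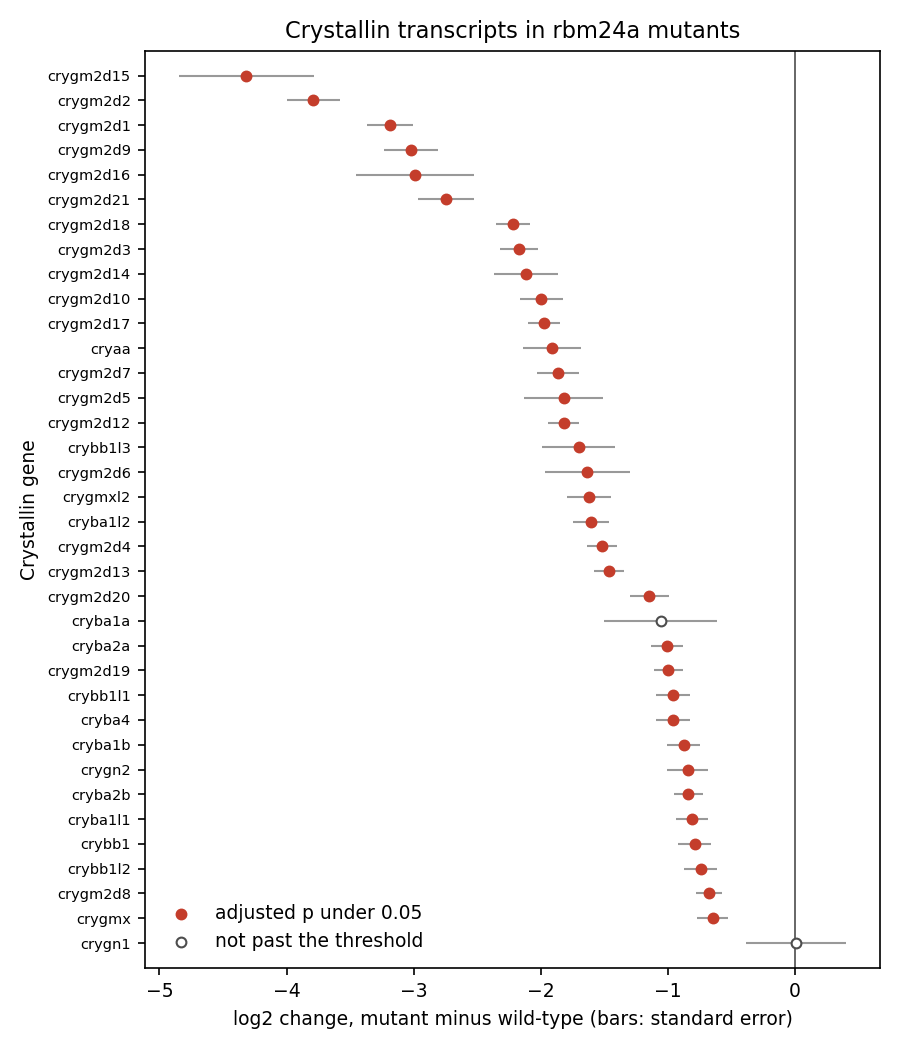
Log2 change of each of the 36 tested crystallin genes, mutant minus wild-type, with bars for the standard error and filled points for genes past the threshold. All 34 filled points lie below 0.

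Transcripts of the contractile apparatus of skeletal muscle were higher in the mutants. Of 75 tested genes of this list, 27 rose and 2 fell, with a median log2 change of 0.34. Murcb, a muscle cavin, rose from 12.7 ± 0.425 to 24.8 ± 0.476 FPKM (SD, n = 3 each), a log2 change of 1.02 (SE 0.10). Myhz1.3, a fast myosin heavy chain, changed by 0.92. The genes that fell were smyhc2, a slow myosin heavy chain, at -3.14 and actn2b, an alpha-actinin, at -1.51. Camera called the list higher (adjusted p = 6.51e-09), a call lost with an adjusted p = 0.786 with an estimated correlation. Fry called it higher (adjusted p = 0.0487). Adjusted over the list alone, 39 genes were higher and 3 lower, and without mutant replicate 2, over all genes, 45 were higher and 5 lower.

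Heart genes did not move as a group, with 5 of 30 tested genes higher and 3 lower (camera adjusted p = 0.504; 5 and 3 adjusted over the list alone). Actc1a (ENSDARG00000042535), an alpha-cardiac actin, fell from 82.1 ± 9.49 to 1.65 ± 0.0666 FPKM (SD, n = 3 each), a log2 change of -5.58 (SE 0.14). Its relative ACTC1 (1 of many) rose by 0.98, as did smyd1b by 0.68, nkx2.7 by 0.81, tnnc1a by 0.53 and myl4 by 0.64. Vmhc, the ventricular myosin, changed by -0.41 and hspb7 by -0.73. Without mutant replicate 2, 8 heart genes were higher and 6 lower. Actin genes are similar in sequence, so reads can be split between copies. Of 25 tested myogenic factors, meox1 (0.51) and myod1 (0.55) rose and mef2ca (-0.93) fell, and camera did not call the list (adjusted p = 0.882; 3 higher and 1 lower adjusted over the list alone), with 3 higher and 3 lower without mutant replicate 2.

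Markers of myeloid cells, the neutrophils and macrophages, were higher. Of 26 tested genes 11 rose and 0 fell, with a median log2 change of 0.50. Lyz, the lysozyme gene, rose from 119 ± 8.52 to 169 ± 2.39 FPKM (SD, n = 3 each), a log2 change of 0.56 (SE 0.11). Npsn rose by 0.64 and mpx, the neutrophil myeloperoxidase, by 0.82. Camera called the list higher (adjusted p = 0.000311), a call lost with an adjusted p = 0.743 with an estimated correlation. Fry called it higher (adjusted p = 0.0209). Adjusted over the list alone, 11 genes were higher and 1 lower.

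Genes of the glucocorticoid response rose in 6 of 16 tested members and fell in 0. Mt2, a metallothionein, changed by 0.93 (SE 0.10), cebpb by 0.74, g6pca.1, a glucose-6-phosphatase, by 1.86 and igfbp1a by 0.69. Camera called the list (adjusted p = 0.00869), a call lost with an adjusted p = 0.829 with an estimated correlation and not made by fry (adjusted p = 0.122). It was also lost without mutant replicate 2 (camera adjusted p = 0.0731, with 0.000241 to 0.829 over all alternatives), a library in which this list had a median log2 difference of 0.20 from the other mutants. Adjusted over the list alone, 8 genes were higher and 2 lower.

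Transcripts of the mitochondrial genome fell in 5 of 13 tested members and rose in 0. All 5 encode subunits of respiratory complex I, namely mt-nd1 (-0.48), mt-nd4 (-0.52), mt-nd4l (-0.56), mt-nd5 (-0.60) and mt-nd6 (-0.51) on the log2 scale. Camera called the list lower (adjusted p = 0.00869), a call lost with an adjusted p = 0.754 with an estimated correlation. Fry called it lower (adjusted p = 0.0134). Adjusted over the list alone, 6 were lower and 0 higher, and without mutant replicate 2, over all genes, 8 were lower and 2 higher.

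Erythroid genes went both ways. Hbbe1.1 (ENSDARG00000089963), an embryonic beta-globin, fell from 209.7 ± 8.10 to 10.5 ± 1.06 FPKM (SD, n = 3 each), a log2 change of -4.26 (SE 0.13), and hbae1, an alpha-globin, fell by 2.75 on the log2 scale. Another 12 of 38 tested genes rose, among them uros by 1.15 and alad by 0.93, which act in heme synthesis. Camera did not call the list (adjusted p = 0.0515; 18 higher and 2 lower adjusted over the list alone), with adjusted p between 5.41e-05 and 0.829 over the alternatives. It was called higher without wild-type replicate 2 (camera adjusted p = 0.0304), mutant replicate 1 (0.0358) or mutant replicate 3 (0.0109). Without mutant replicate 2, 19 were higher and 3 lower. Globin genes have near-identical copies, so these values are uncertain.

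Heat shock genes were not called as a list (camera adjusted p = 0.236; 3 higher and 1 lower adjusted over the list alone). Among 33 tested, hsp70l (1.81), dnaja1 (0.91) and hspd1 (0.46) rose and ahsa1b (-0.66) fell. In mutant replicate 2 heat shock genes had a median log2 difference of -0.36 from the other mutants, and without that library camera called the list higher (adjusted p = 0.00433, with up to 0.951 over the alternatives), with 11 genes higher and 2 lower. Ribosomal protein genes differed by -0.56 in that library, and of 82 tested 0 rose and rps27.1 (-0.93) and rpl37 (-0.49) fell. Camera did not call them (adjusted p = 0.144; 0 higher and 1 lower adjusted over the list alone), and without mutant replicate 2 it called them higher (adjusted p = 1.95e-11, with up to 0.951 over the alternatives), with 59 genes higher and 2 lower. Without wild-type replicate 1 camera also called them higher (adjusted p = 0.00208).

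**Figure D3:**
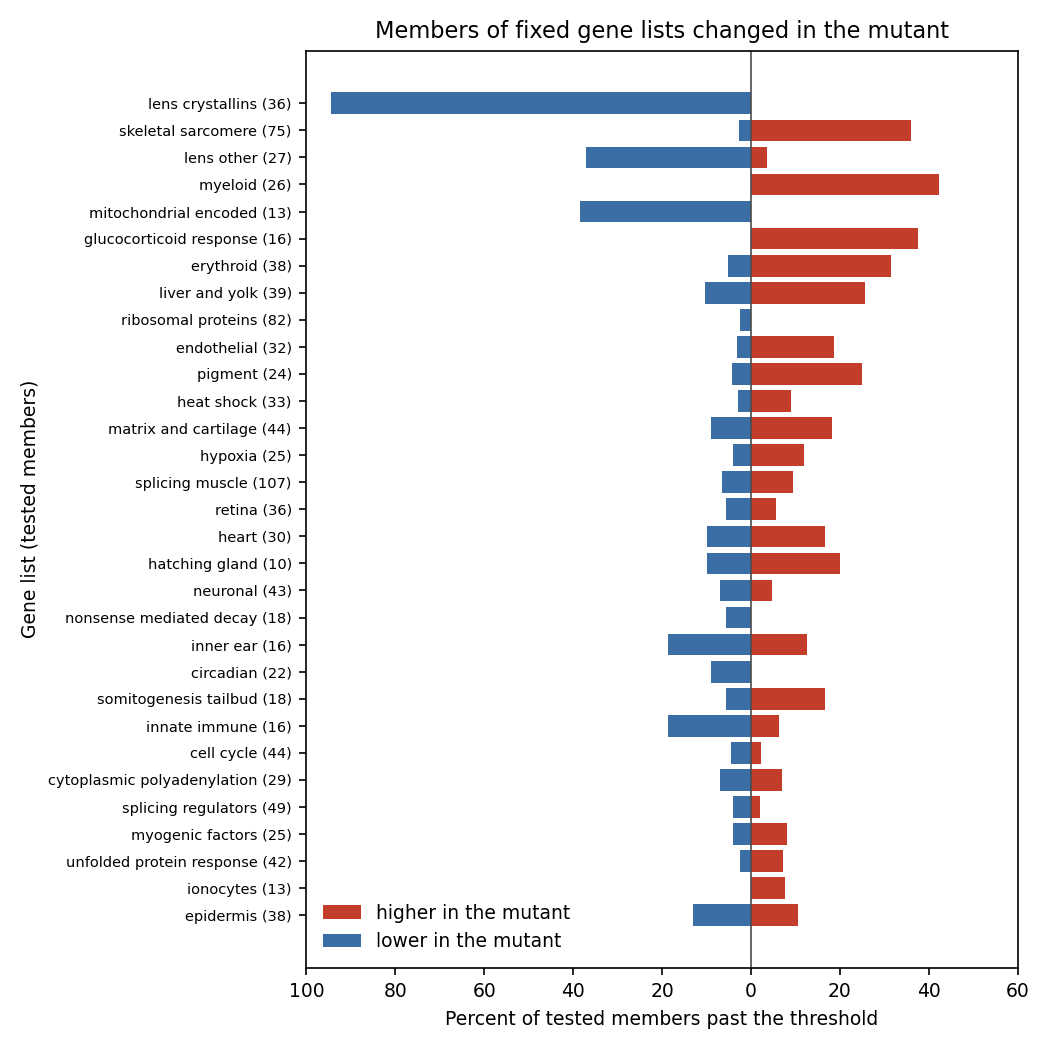
Percent of tested members of each gene list reported here that passed the threshold, to the right for genes higher and to the left for genes lower in the mutant, with the number tested in parentheses. The crystallins extend farthest to the left, with 34 of 36 lower.

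None of the RNA processing lists was called by camera with its preset correlation. Of 49 tested splicing regulators rbm24a rose, and rbpms2b (-0.72) and srsf1b (-0.47) fell (camera adjusted p = 0.877; 1 higher and 2 lower adjusted over the list alone). Of 29 tested genes of cytoplasmic polyadenylation, fam46ba (0.68) and ddx6 (0.44) rose and lsm14aa (-1.19) and eif4eb (-0.43) fell (camera adjusted p = 0.873; 2 higher and 2 lower adjusted over the list alone). Cpeb1b had 6, 9 and 19 reads in wild-type and 10, 8 and 7 in mutant embryos, and pabpc1l 2, 1 and 0 against 1, 0 and 0, both below the expression filter. Of 18 tested genes of nonsense-mediated decay smg6 (-0.48) fell (camera adjusted p = 0.727; 0 higher and 1 lower adjusted over the list alone). The unfolded protein response had ddit4 (0.87), atf3 (0.89) and slc3a2b (0.47) higher and ppp1r15a (-0.66) lower of 42 tested (camera adjusted p = 0.898; 3 higher and 1 lower adjusted over the list alone). Without mutant replicate 2, the genes higher and lower were 7 and 9 for splicing regulators, 5 and 8 for the unfolded protein response, 5 and 2 for cytoplasmic polyadenylation and 1 and 2 for nonsense-mediated decay.

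The 10 largest rises among named genes, on the log2 scale, were ptpdc1b (5.21), znf1117 (4.37), fabp7b (3.22), MFAP4 (1 of many) (2.73), pth1a (2.60), snap29 (2.36), znf1143 (2.29), fads2 (2.25), SNORA21 (2.21) and dao.2 (2.18). Fabp7b encodes a fatty acid binding protein, pth1a a parathyroid hormone, snap29 a SNARE protein and fads2 a fatty acid desaturase. Ptpdc1b was at 0.247 ± 0.0379 FPKM in wild-type and 8.87 ± 0.218 FPKM in mutants (SD, n = 3 each). Among the largest falls, larsa had 66 reads in the wild-type libraries and 0 in the mutants, which is at least 22.6-fold lower, and snoU2_19 had 40 reads against 0, at least 13.7-fold lower. The others were mal (-5.63), actc1a, prkd2 (-4.45), fkbp16 (-4.41), crygm2d15 (-4.32), hbbe1.1, SNORD72 (-3.93) and crygm2d2. The zinc finger genes belong to large families with similar copies and are uncertain.

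Over all 16489 genes tested, 1107 were higher and 1234 lower in the mutants, 2341 in all, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The groups did not overlap for 30.5% of all genes tested, against 10% by chance. The count was 1383 without wild-type replicate 1, 1367 without wild-type replicate 3 and 4828 without mutant replicate 2. With a minimum of 5 FPKM 1431 genes passed, and with a minimum change of 2-fold 853.

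The authors' deposited table of changed genes holds 743 genes, 304 higher and 439 lower in the mutants. Here 589 genes of the authors' deposited table were tested, and all 589 were called in the same direction, while 154 were below the expression filter. Another 1752 genes called here were not in the authors' deposited table, whose genes all had an adjusted p under 0.01 and at least a 2-fold change. The authors' deposited table gives log2 changes of -5.13 for actc1a, -4.10 for hbbe1.1, 4.57 for ptpdc1b and -2.95 for crygm2d1. Sizes differed more for other genes, with -2.30 in the authors' deposited table against -4.32 here for crygm2d15 and -1.47 against -4.04 for psmb9a.

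Exons were both skipped and included more often in the mutants, with skipping more frequent. At an FDR under 0.05 the authors' deposited table of skipped exons lists 1816 events in 1296 genes, 997 with lower and 819 with higher inclusion in the mutants. This FDR was taken as given and can be very small on few reads. An exon of camk2b1 had an FDR of 6.19e-43 in the authors' deposited table, with 8 wild-type and 12 mutant reads. Of 688 skipped exons with at least 20 reads in every library, 270 (39.2%) had levels that did not overlap between the groups. With 1 event per gene, 704 genes of the authors' deposited table had lower and 592 higher inclusion (two-sided exact sign test, p = 0.00204). For alternative 5' splice sites the authors' deposited table gives 294 events lower and 358 higher, or 252 and 315 genes (exact sign test, p = 0.00916). Retained introns in the authors' deposited table were lower in 83 and higher in 105 events (71 and 92 genes, exact sign test, p = 0.117), and mutually exclusive exons in 225 and 274 (139 and 170 genes, exact sign test, p = 0.0877). Neither of these types passed. For mutually exclusive exons, lower means less of 1 exon of a pair and more of its partner, so the direction there is a switch. The call on alternative 5' splice sites of the authors' deposited table was lost for changes of at least 10 percentage points (exact sign test, p = 0.0854) and for levels that do not overlap (exact sign test, p = 0.25). Alternative 3' splice sites are held here only in part, with 556 events of the authors' deposited table, all lower.

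The largest loss of a skipped exon with at least 20 reads in every library was in matn4, a cartilage matrix protein gene. By the authors' deposited table its 123 bp exon (GRCz11, chromosome 6, 52826564 to 52826686) changed by -49.6 percentage points, from levels of 0.646, 0.894 and 0.764 to 0.223, 0.164 and 0.428. Exons of srsf6a (-32.7), a splicing factor gene, nenf (-28.6), slc13a4 (-26.5) and GTSF1 (1 of many) (-25.9) followed in the authors' deposited table, in percentage points. Wild-type levels of srsf6a in the authors' deposited table spread from 0.129 to 0.896. The authors' deposited table also lists 3 exons of cyt1l, a keratin gene with near-identical tandem copies, which are uncertain, at -43.4, -28.3 and -26.7 percentage points. Higher inclusion in the authors' deposited table was found for rpl14 (52.1), ktn1 (37.2), sh2b1 (25.8), srek1 (24.6), rtkn2a (22.8), scarb1 (22.6), hoxa3a (21.4) and mrpl30 (19.5), in percentage points. For rpl14, mutant levels of 1.0, 0.221 and 1.0 overlap wild-type levels of 0.184, 0.164 and 0.31 in the authors' deposited table.

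**Figure D4:**
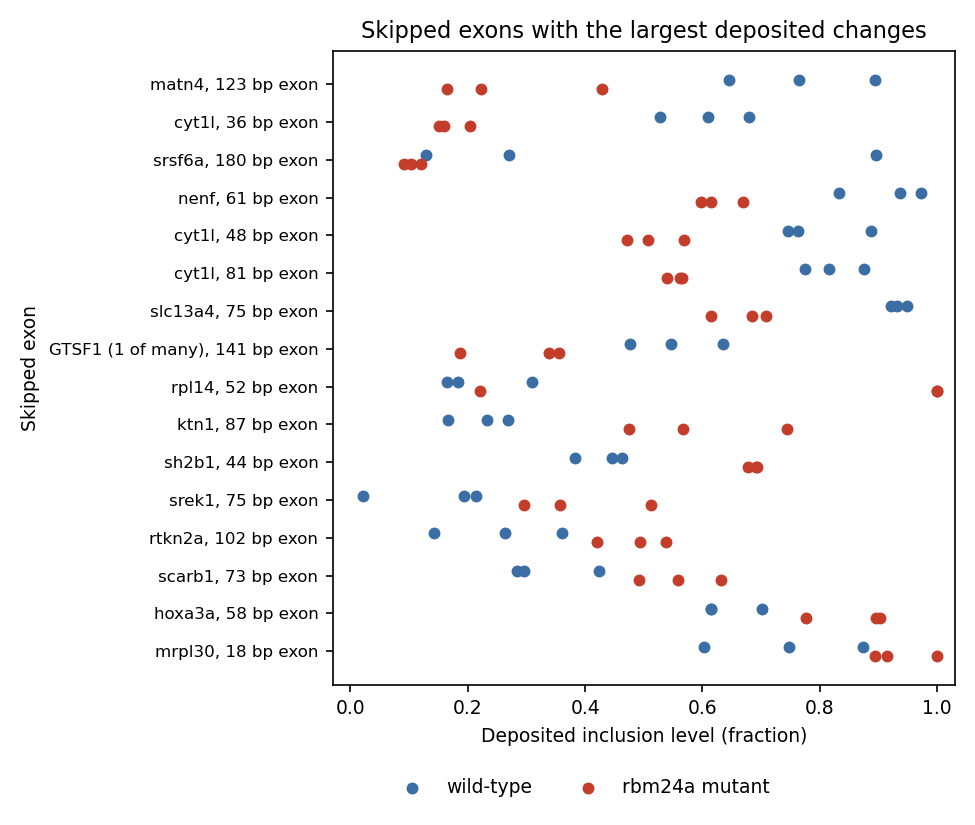
Inclusion level of each skipped exon from the authors' deposited table as a fraction, 1 point per library, for the 8 largest changes in each direction. The matn4 exon has wild-type levels from 0.646 to 0.894 and mutant levels from 0.164 to 0.428.

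An intron of gas5 (GRCz11, chromosome 8, 16574469 to 16574642), a host gene of small nucleolar RNAs, was retained at 0.77, 0.631 and 0.657 in mutants against 0.033, 0.023 and 0.038 in wild-type embryos by the authors' deposited table. The gas5 transcript fell by 1.57 on the log2 scale in the counts. Other introns in the authors' deposited table changed by 31.3 (ndufb7), -25.3 (puf60a) and -24.2 (mibp) percentage points. The ndufb7 event had 276 reads in wild-type and 2445 in mutants in the authors' deposited table, while its gene changed by 0.69 on the log2 scale. That mismatch makes its value uncertain, and its cause was not tested. Mutually exclusive exons in the authors' deposited table changed by 42.4 in matn4, -35.7 in hbbe1.1 and -34.3 in cyt1l, in percentage points, and the copies of hbbe1.1 and cyt1l make those values uncertain. Alternative 5' splice sites in the authors' deposited table changed by 33.9 (ubap2l), 33.3 (hhla2a.1), -18.7 (tmem186) and -17.6 (tjp1b) percentage points. Alternative 3' splice sites in the authors' deposited table changed by -72.6 (tssc4) and -64.2 (kif14) percentage points. Levels of puf60a and tjp1b in the authors' deposited table overlapped between the groups.

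Genes of muscle and the cytoskeleton that are spliced in a tissue-specific way were examined because Rbm24 is known to promote the inclusion of muscle exons. Of 50 such genes with a skipped exon in the authors' deposited table, 21 had lower and 29 higher inclusion, against 683 and 563 of other genes (two-sided Fisher's exact test, odds ratio 0.597, p = 0.0829), which did not pass. By the authors' deposited table, exons changed in mef2d by 37.4, in mybpc3 by 30.0, in neb by 4.5 and in plecb by -19.4 percentage points. Exons of ablim1b in the authors' deposited table changed by 27.7, -15.7 and -18.6, and an exon of camk2b1 changed by -49.0 with a library at 0 reads. In the authors' deposited table the levels of plecb, mybpc3, camk2b1 and the ablim1b exons at -15.7 and -18.6 overlapped between the groups, and libraries had as few as 6 reads for mybpc3 and 3 for mef2d. In the expression counts this list had 10 of 107 tested genes higher and 7 lower (camera adjusted p = 0.332; 10 and 7 adjusted over the list alone), with smtnl1 at 1.59, capzb at 0.72 and sgcg at -2.37. Without mutant replicate 2, 24 were higher and 16 lower, and with a minimum of 5 FPKM camera called the list higher (adjusted p = 0.016, with up to 0.951 over the alternatives). Genes of the authors' deposited table of splicing events were changed in expression in 294 of 2231 cases, against 316.7 for independent sets (two-sided Fisher's exact test, odds ratio 0.905, p = 0.142). With a minimum of 5 FPKM this Fisher's exact test on the authors' deposited table gave an odds ratio of 0.823 and p = 0.024. The background took in genes that could not be scored for splicing, and alternative 3' splice sites were held only in part. These odds ratios thus do not show whether spliced genes change in expression less often.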

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

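Scaling by library totals alone, list matching by the table's symbols alone and muscle splicing members by exact symbol were chosen after seeing the data, the other settings before. Of 2658 values of 142 named genes under the alternatives, 2423 kept their direction and side of the threshold, 181 lost the call, 51 gained it and 3 reversed. Of the 127 called genes 93 kept the call in each alternative and 0 reversed. The reversals were rbm24b, not called, at -0.26, -0.06 and -0.52 on the log2 scale without wild-type replicate 1, wild-type replicate 3 and mutant replicate 2, with a highest value of 0.66. At this depth and spread between replicates, whose parts were not separated, 29 of 50 simulated 1.5-fold changes were missed.

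The count of 2341 genes (1107 higher, 1234 lower) was 1431 (693, 738) with a minimum of 5 FPKM, where fewer genes are tested, and 853 (375, 478) with a 2-fold minimum. Leaving out 1 library gave 1367 to 4828 genes, 640 to 2393 higher and 727 to 2435 lower, with the highest values without mutant replicate 2. Without filter it was 3098, with DESeq2 2262. Library totals alone gave 805 higher and 1195 lower, and limma on log2(FPKM + 1) 850 and 1303. Whether the shared replicate numbers mark paired samples was not settled. Deviations correlated at 0.19, 0.32 and 0.05 for numbers 1, 2 and 3, and wild-type replicate 3 correlated best with mutant replicate 1 (0.16), the others with their own number. Different numbers correlated between -0.31 and 0.16. With a replicate block the count was 3387, which included all 2341 genes called without it, and 7 lists were called.

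The log2 change of rbm24a lost its call at 0.74 with library totals alone (adjusted p = 0.0501) and at 0.60, 0.65 and 0.68 with limma (pseudocounts of 1, 0.5 and 0.1 FPKM; adjusted p of 0.0711, 0.0685 and 0.0676). The cause was not tested. It lay between 0.56 and 0.89 on leaving out 1 library, past the threshold each time. The 6 called lists became 0 with camera and an estimated correlation, which allows for members that vary together, 10 with limma and a pseudocount of 0.1, and 7 to 10 on leaving out 1 library. The list of erythroid genes passed with the table's symbols alone, with limma and quantile scaling, with limma and a pseudocount of 0.1, with the block, and without wild-type replicate 2, mutant replicate 1 or mutant replicate 3. Ribosomal protein genes passed with limma and a pseudocount of 0.1 (camera adjusted p = 0.0381). Of the 6 called lists, the glucocorticoid list did not pass by fry (adjusted p = 0.122), and the others did (adjusted p between 0.0134 and 0.0487).

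From the authors' deposited table, 3155 events over the types held in full became 1850 with a change of at least 10 percentage points, 1221 with at least 20 reads in every library and 1094 with separate levels. In that order, lower and higher events of the authors' deposited table became 578 and 461, 392 and 296, and 354 and 227 for skipped exons; 46 and 61, 43 and 36, and 27 and 42 for retained introns; and 123 and 142, 113 and 182, and 80 and 125 for mutually exclusive exons (139 and 170 with 1 event per gene). For alternative 5' splice sites of the authors' deposited table, higher events became 236 at 10 percentage points, and lower and higher became 67 and 92, then 110 and 129. Leaving out 1 level of the authors' deposited table gave 951 to 980 lower and 768 to 827 higher skipped exons, 77 to 85 and 92 to 103 retained introns, 213 to 229 and 265 to 272 mutually exclusive exons, and 278 to 285 and 322 to 347 alternative 5' splice sites.

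The share of genes with lower inclusion in the authors' deposited table reversed for retained introns to 56.9% (exact sign test, p = 0.321) at 20 reads and passed at 36.9% (p = 0.0464) for separate levels. It passed for mutually exclusive exons at 45.1% (exact sign test, p = 0.0315) over all events. It was no longer past the threshold for alternative 5' splice sites at 45.5% (exact sign test, p = 0.0854) at 10 percentage points and 45.9% (p = 0.25) for separate levels. The overlap of spliced and changed genes passed with an odds ratio of 0.823 (Fisher's exact test, p = 0.024) at 5 FPKM, against a background that includes genes that could not be scored for splicing. Of 228 values of 38 named events of the authors' deposited table on leaving out 1 level, 1 reversed, plecb, which lay between -37.4 and 0.7 percentage points. For muscle genes of the authors' deposited table, exact symbols and an FDR under 0.01 gave an odds ratio of 0.528 (Fisher's exact test, p = 0.0484), past the threshold, where p lay between 0.058 and 0.312 in the other settings. The cause of these shifts was not tested. Events with a library at 0 or 1 read made up 28.9% of skipped exons and 44.8% of alternative 5' splice sites in the authors' deposited table.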

Other observations

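Further tissue lists held changed genes without a call by camera at the main setting. Of 36 tested retina genes atoh7 (-1.69), which retinal ganglion cells need, and foxn4 (-0.55) fell, and rbp4l (0.54) and hmx1 (0.48) rose (camera adjusted p = 0.435; 1 higher and 2 lower adjusted over the list alone). Fry called the retina list lower (adjusted p = 0.0303). Of 16 tested inner ear genes s100s (-1.62), s100t (-0.66) and stm (-0.68), an otolith matrix gene, fell, and otomp (0.65) and oc90 (0.40) rose (camera adjusted p = 0.75; 3 higher and 3 lower adjusted over the list alone). Of 24 tested pigment genes 6 rose, among them pmela (0.70), tyrp1b (0.58) and pah (0.55), and PTS, of pterin synthesis, fell by 3.30 on the log2 scale (camera adjusted p = 0.236; 7 higher and 1 lower adjusted over the list alone). With limma, camera called the pigment list higher after quantile scaling (adjusted p = 0.0351) and with a pseudocount of 0.1 FPKM (adjusted p = 0.0212), with up to 0.884 over the alternatives. Of 32 tested endothelial genes 6 rose, among them pecam1 (0.86), flt4 (0.52) and cdh5 (0.61), and klf2a (-0.75), which responds to blood flow, fell (camera adjusted p = 0.165; 7 higher and 1 lower adjusted over the list alone). Without mutant replicate 3 camera called the endothelial list higher (adjusted p = 0.0299, with up to 0.951 over the alternatives). Of 43 tested neuronal genes stmn2b (0.57) and sncga (0.44) rose and nefmb (-0.85), gng3 (-0.44) and tubb5 (-0.33) fell (camera adjusted p = 0.545; 2 higher and 2 lower adjusted over the list alone).

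Of 39 tested liver and yolk genes 10 rose, with cp, the ceruloplasmin gene, at 2.14, and afp4 (-0.95), serpina1 (-0.70), apoa1b (-0.77) and apoa2 (-0.47) fell (camera adjusted p = 0.128; 13 higher and 5 lower adjusted over the list alone). Camera called this list higher without mutant replicate 3 (adjusted p = 0.000333) and without wild-type replicate 3 (adjusted p = 0.0494), with up to 0.951 over the alternatives. Of 44 tested matrix and cartilage genes 8 rose, among them col9a1b (0.73), col9a3 (0.57), col2a1a (0.54) and col9a2 (0.46), and col9a1a (-0.72), col5a1 (-0.45), col5a2a (-0.32) and sox9b (-0.36) fell (camera adjusted p = 0.312; 10 higher and 5 lower adjusted over the list alone). In the epidermis list epcam (0.82), anxa1a (0.66), cldnb (0.47) and krt15 (0.56) rose and anxa1b (-1.49), krt17 (-1.11), cldne (-0.74), cyt1 (-0.65) and krt91 (-0.41) fell, of 38 tested (camera adjusted p = 0.976; 5 higher and 6 lower adjusted over the list alone). Ca15a (0.44) was the called ionocyte gene of 13 tested (camera adjusted p = 0.898; 0 and 0 adjusted over the list alone). In the hatching gland list agr2 (0.96) and klf17 (0.49) rose and ctslb (-0.52) fell of 10 tested (camera adjusted p = 0.545; 4 higher and 1 lower adjusted over the list alone). Cdca8 (0.53) rose and mki67 (-0.59) and a copy of rrm2 (-0.40) fell of 44 tested cell cycle genes (camera adjusted p = 0.873; 1 higher and 1 lower adjusted over the list alone), a list with a median log2 difference of -0.29 in mutant replicate 2 from the other mutants. Circadian genes had ciarta (-0.60) and nfil3-5 (-0.48) lower of 22 tested (camera adjusted p = 0.75; 0 higher and 2 lower adjusted over the list alone). Hypoxia genes had higd1a (1.21), eno1a (0.62) and igfbp1a (0.69) higher and ldha (-0.37) lower of 25 tested (camera adjusted p = 0.312; 3 higher and 1 lower adjusted over the list alone). Innate immune genes had cxcl18b (1.39) higher and psmb9a (-4.04), irf1b (-0.64) and mhc1uba (-2.15) lower of 16 tested (camera adjusted p = 0.835; 1 higher and 3 lower adjusted over the list alone). In the tailbud list aldh1a2 (0.39), ta (0.91) and tbx6l (0.89) rose and her12 (-0.40) fell of 18 tested (camera adjusted p = 0.78; 3 higher and 1 lower adjusted over the list alone). Median and mean log2 changes differed in sign in the lists of myogenic factors, cytoplasmic polyadenylation, inner ear, hatching gland, epidermis, ionocytes and cell cycle. Without mutant replicate 2, the genes higher and lower over all genes tested were 8 and 11 in the epidermis list, 10 and 5 for the cell cycle, 2 and 6 for the retina, 2 and 7 for neurons, 11 and 8 for liver and yolk, 10 and 8 for matrix and cartilage, 1 and 4 for ionocytes, 4 and 4 for the inner ear, 9 and 2 for pigment, and 4 and 3 for hypoxia.

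All tests in the following paragraphs were chosen after the results they bear on were seen, with none of their bounds set in advance. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real count of 2341, namely the real split, and the highest of the other splits gave 0 by edgeR. The splits are too few for a share under 0.05.

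Crystallins fell together but not by the same factor. A lower share of lens fibre cells as the whole cause would lower all of them alike under some conditions. They must be expressed in those cells alone and evenly among them, which was not tested. The log2 changes of the 16 tested crystallins outside the crygm2d family varied by more than their standard errors allow (heterogeneity Q of 79.6 over 15 degrees of freedom). If fibre cells differ in their crystallins, this cannot decide about that cause. Of 27 other lens genes tested, 10 were lower and 1 higher, and a lower share of fibre cells could also give that. Reads shared among crygm2d copies may blur the single values, but those outside that family had a median log2 change of -0.916, with 14 of 16 lower. The mutation, the group of the design, stays open as an untested biological explanation, as does a loss of lens cells, as a part or the whole of the cause.

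Mutant replicate 2 stood apart from the other mutants, and 4828 genes passed without it. A gene length trend may contribute, but with the trend removed from each library 2505 genes passed with this replicate and 5322 without it. Sequencing depth as the cause is argued against by the totals, since that of replicate 2 was 0.986 times that of mutant replicate 1 and the total of replicate 3 was 1.138 times. Wild-type embryos mixed into the sample, as the whole cause, would place this replicate between the groups. With the length trend removed, 44 of the 57 genes at least 2-fold apart from the other mutants (77.2%) lay outside the range of the other 5 libraries. Each other library had 2 to 5 such genes by the same test, which were 40% to 100% of its genes 2-fold apart. That share was thus not particular to this replicate, and the argument rests on the number of genes and covers those 44 alone. A small share of wild-type embryos stays open. Its size is limited by actc1a, which was high in the wild-type libraries and low in all mutants, with little spread between them. This covers that gene alone, and embryos that express it like the wild-type group. The replicate was nearer to wild-type on the leading principal component (31.5, the other mutants at 39.7 or more). Its crystallins went the other way, at 0.170% of reads against 0.182% and 0.171% in the other mutants and 0.322% or more in wild-type. A difference in stage, clutch or handling also stays open and was not tested. So does a different allele, since the labels place the deletion in a different exon for each mutant library.

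Changed genes lay next to each other more often than by chance, in 407 pairs against a mean of 254.6 over 10000 permutations. Tandem families as the whole cause are argued against by 274 pairs of different name families against 201.2 (p = 0.0001, the smallest the permutations can give), though among genes changed at least 4-fold such pairs numbered 2 against 1.2. Linkage to rbm24a as the whole cause is argued against by 249 pairs against 192.7 with its chromosome left out, while a part from linkage stays open, since 18.3% of genes on that chromosome were changed against 13.3% elsewhere (two-sided Fisher's exact test, p = 0.00083, which treats neighbours as independent), but it ranked 3 of 25 chromosomes, below others at 19.1% and 18.6%, and 20 of the 100 nearest genes were changed against 13.4% of the rest (Fisher's exact test, p = 0.076). Changed neighbours of different families moved the same way in 70.8% of pairs (194 of 274) against a mean of 137.0 pairs for permuted directions. In a window of 40 genes around apoa1bp, which is 432 genes from rbm24a on its chromosome, 22 were changed and all were lower, among them mhc1uba, psmb9a and s100s. This window was picked among those richest in changed genes, and others held changes in both directions, such as 7 higher and 13 lower in another. Sequence or copy differences between the parents of the groups may give blocks of changed neighbours, and cannot be told apart from shared regulation of neighbours, because no variant data were analysed here and parentage is not in the labels.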
